A study of Homo sapiens with 14 samples.

How the data were processed

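RNA was measured on 14 Affymetrix arrays, 1 per RNA sample. HEK 293T cells on plates were transfected by calcium phosphate with plasmids for tagged AGO2 and lysed in NET buffer. AGO2 was precipitated with anti-FLAG M2 agarose, and RNA of precipitates and lysates was extracted with TRIzol, all per the labels' protocols. Labelled cDNA was made with the WT PLUS kit from differing amounts of precipitate RNA, with ERCC spike-ins added in volumes adjusted to the RNA amount, per the labels' protocols. The labels' cell line field reads HEK293 and their other fields HEK 293T. Groups were taken from the sample titles: 3 inputs (WT, Phos3A and Phos3E, 1 each) and 11 precipitates (WT, Phos3A and Y529E with 3 replicates, Phos3E with replicates 1 and 3). Phos3E replicate 2 and a Y529E input were not analysed here. With 2 or 3 arrays per group the number of arrays limits the precision. The labels do not say what a replicate shares with another, so p values measure the spread between these samples, which may be technical.

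The deposited values are log2 levels of 53617 probe sets, which the authors normalized by a variance stabilizing method on the ERCC spike-ins, separately for inputs and precipitates, per the labels' series design text. R 3.3.0, oligo and limma were used, per the submitters' processing notes, and how probes were summarised is not stated there. The log base was read from the range of the values. At 5 decimals 49.7% of probe sets had identical values on all 3 inputs (58.6% to 59.9% for pairs of inputs), against 0.144% to 2.85% for pairs of precipitates. The cause was not tested, so inputs are described without a test and their small differences carry little information.

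Of the probe sets 23871 had 1 gene symbol, 1842 had several and 27904 had none in the annotation used. The latter 2 kinds were left out. Entrez IDs matched 22569 to RefSeq genes, and 90 symbols were updated. For 22395 genes the probe set with the highest mean over the precipitates was kept. Genes were tested if that mean exceeded the 75th percentile of 27 markers of other cell types on the array (log2 level 4.75), which left 15341. A stricter filter used the highest marker (5.43) and left 10181.

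Each of 6 comparisons between precipitates was a contrast in 1 limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) over all 11 arrays and 4 groups. Phos3E has 2 arrays and shares the spread of the other groups. The 6 comparisons share arrays and are not independent. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The differences between per-array medians were tested by exact two-sided permutation. Each comparison was also run with every array centred on its median gene. Differences between 2 mutants were tested as contrasts, whereas an effect past the threshold in one mutant and not in another is not shown to differ. Inputs were compared as log2 differences over 14105 genes. Ratios of precipitate over input used the mean of the precipitates minus the input of the same construct minus the median of that difference over 13657 genes (removed medians -0.32 for WT, -0.17 for Phos3A and -0.63 for Phos3E).

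The 20 gene lists were microRNA precursors, targets of let-7, of the miR-17 family and of the miR-15, miR-19, miR-25 and miR-30 families, microRNA pathway components, the Argonaute phosphorylation cycle, replication-dependent histones, cytosolic ribosomal proteins, mitochondrially encoded RNAs, snoRNAs and scaRNAs, spliceosomal and related RNAs, nuclear oxidative phosphorylation genes, zinc finger (ZNF) genes, nuclear-retained long noncoding RNAs, immediate early and AU-rich mRNAs, heat shock and unfolded protein response genes, interferon response genes, p53 targets, mitotic genes and markers of other cell types. The target lists were written from general knowledge, not from predicted sites. They were tested with limma's camera at a preset correlation of 0.01 and again with the correlation estimated per list, adjusted over the lists of a comparison. At the preset correlation 12, 9, 14, 10, 9 and 9 lists passed in the comparisons in the order of the report, and 0 passed in any with an estimated correlation. camera compares a list with the other genes. Counts adjusted over the list alone used the list's own genes. Percentiles came from 10000 random lists of the same size, matched on mean level, or on the input level for ratios over input.

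Named genes followed a rule. AGO2, AGO1, AGO3, AGO4, TNRC6A, TNRC6B and TNRC6C were always named. In each comparison the rule took up to 10 called genes each way with the largest differences and arrays that did not overlap, up to 3 small RNA genes each way, and up to 2 members each way of each list that passed. The report gives examples from these. How to apply the rule to list members was settled after the data were seen: where a comparison had called genes, only called members were named, and in Phos3A minus WT and Phos3E minus WT, with none, members with the largest differences were given as values. Groups, lists, tests, threshold, filter and most alternatives were fixed before the data were examined. Added afterwards were cyclic loess, centring combined with an estimated correlation, and a wide histone pattern. The histone pattern was narrowed to replication-dependent genes after the symbols on the array were seen. Symbols in the lists were matched through synonyms, and a current symbol was never read as a synonym of another gene, a correction made after first results were seen.

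Same-numbered replicates were not treated as pairs. Of 15 such pairs the correlations ran from -0.606 to 0.361, and the 2 above 0.1 were Phos3A with Phos3E, where pairing stays open. The other alternatives were quantile normalization, no filter, the stricter filter, the mean over probe sets, a variance trend with robust estimation, array weights, fits to only the 2 groups, a minimum difference, subtraction of the input and leaving out each array.

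The fit was tested on simulated data with 200 of 15341 genes changed in each comparison. At true log2 differences of 1 it recovered 79.1%, 85.1%, 74.6%, 64.2%, 82.1% and 73.1% in the comparisons in report order. At 0.5 these were 17.9%, 10.4%, 10.4%, 2.99%, 22.4% and 5.97%, and at 2 at least 98.5% in each. False calls numbered 9, 5, 5, 9, 8 and 13, and 1 of 50 random lists had an unadjusted p under 0.05. These rates were not tested under array offsets or the lists' estimated correlations (0.23 to 0.91). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.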

Results

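HEK 293T cells (1 label field reads HEK293) were transfected with human AGO2 carrying FLAG and HA tags. The protein was wild type (WT) or carried 1 of 3 sets of substitutions: Phos3A and Phos3E, with alanine or glutamate at a cluster of phosphorylation sites near the carboxyl terminus, and Y529E, with glutamate at a tyrosine needed for small RNA binding. Argonaute proteins carry microRNAs to partly complementary mRNAs, and the design asks which RNAs come down with each form of AGO2. RNA from anti-FLAG precipitates was measured on 11 arrays (WT n = 3, Phos3A n = 3, Phos3E n = 2, Y529E n = 3), and lysate RNA (input) on 3 arrays, 1 each for WT, Phos3A and Phos3E. A Y529E input, a precipitate from cells without tagged AGO2 and Phos3E replicate 2 were not analysed here. Of 22395 genes, 15341 were bright enough to test in the precipitates. The number of arrays limits the precision.

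AGO2, the transfected gene, had a log2 level of 12.13 ± 0.28 in WT precipitates (mean ± SD, n = 3), 12.51 ± 0.27 in Phos3A (n = 3), 11.86 ± 0.18 in Phos3E (n = 2) and 12.44 ± 0.21 in Y529E (n = 3). The WT, Phos3A and Phos3E inputs held 9.12, 9.07 and 9.01. The median over the 15341 genes was 6.27 ± 0.22 in WT, 6.39 ± 0.14 in Phos3A, 5.93 ± 0.18 in Phos3E and 5.94 ± 0.13 in Y529E precipitates. Differences between these medians were -0.33 for Y529E minus WT (exact two-sided permutation p = 0.1), 0.12 for Phos3A minus WT (exact p = 0.5) and -0.34 for Phos3E minus WT (exact p = 0.2). They were 0.46 for Phos3A minus Phos3E (exact p = 0.1), 0.45 for Phos3A minus Y529E (exact p = 0.1) and -0.00 for Phos3E minus Y529E (exact p = 1). No p under 0.1 was possible with these numbers of arrays. Arrays are numbered by replicate below, and without WT-1 the first 3 became -0.21, 0.25 and -0.21. Phos3A minus WT was also 0.04 without Phos3A-3 or WT-3 and 0.08 without WT-2, and Phos3E minus WT -0.21 without Phos3E-1. Phos3E minus Y529E ran from -0.13 to 0.13. With no filter Y529E minus WT was -0.12, Phos3E minus WT -0.17 and Phos3A minus Y529E 0.30. The deposited values were scaled on spike-ins, which leaves such offsets in them. Gene counts are therefore given as deposited and with each array centred on its median gene, and gene lists relative to the median of all genes.

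**Figure D1:**
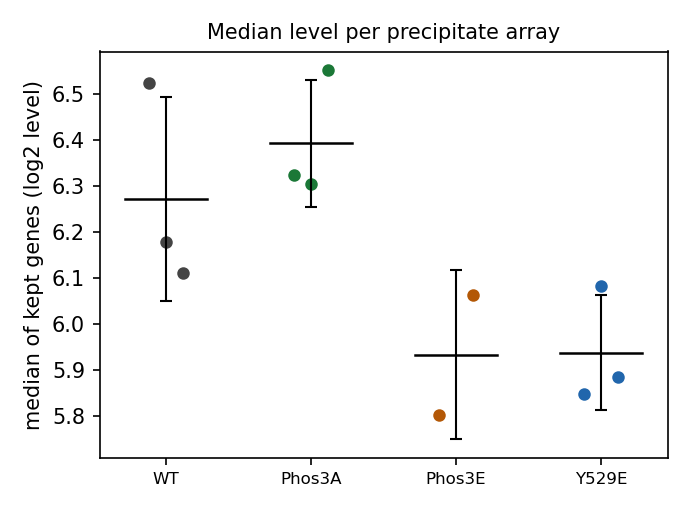
Median log2 level of the 15341 tested genes on each of the 11 precipitate arrays (dots), with group means (lines) and 1 SD (error bars). The Phos3E and Y529E arrays lie between 5.80 and 6.08, and the WT and Phos3A arrays between 6.11 and 6.55.

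Y529E precipitates held less of many mRNAs than WT precipitates. MINK1, which encodes a serine/threonine kinase, fell most, from 10.14 ± 0.34 to 7.98 ± 0.28 (n = 3 each, log2 difference -2.16, SE 0.21, limma adjusted p = 0.000213). Next came MYLIP (-1.89), an E3 ubiquitin ligase for the LDL receptor, PSME3IP1 (-1.83), the orphan nuclear receptor NR6A1 (-1.74), TPRG1L (-1.74) and the helix-loop-helix factor HAND1 (-1.73). They were followed by SMIM10L2B (-1.70), the zinc finger repressor ZBTB4 (-1.65), RBBP9 (-1.65) and EAPP (-1.64). SE lay between 0.18 and 0.25, the highest adjusted p was 0.000421, and each of 3 Y529E arrays lay below each of 3 WT arrays. All 10 passed with the arrays centred, after quantile normalization, after cyclic loess (-1.51 to -1.02) and with any 1 array left out.

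As deposited fewer genes rose, which did not hold after loess (1525 higher, 1302 lower). TFRC, the transferrin receptor, rose from 7.77 ± 0.22 to 8.74 ± 0.34 (0.96, SE 0.24, adjusted p = 0.00772), and NEU1, a lysosomal sialidase, by 0.58 (SE 0.14, adjusted p = 0.00729), each in 3 of 3 arrays and also with any 1 array left out. The other 8 of the 10 largest increases were the secreted glycoprotein STC2 (0.77), the collagen prolyl hydroxylase P4HA1 (0.67), MHENCR (0.64), EMC7 (0.62), SPRY4 (0.58), H3C13 (0.55), SLC38A12 (0.54) and the proton pump subunit ATP6V0A1 (0.52). Their adjusted p ran from 0.0126 to 0.0370, and each lost its call when 1 array was left out. Without Y529E-2 all of them except MHENCR had adjusted p between 0.0719 and 0.150. Without Y529E-1, Y529E-3, WT-1, WT-2 or WT-3, 2 to 7 of the 8 lost it (highest 0.1003). All 10 increases passed under each scaling, with larger values (0.86 to 1.30 when centred, 0.70 to 1.53 after quantile scaling, 0.67 to 1.53 after loess).

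Of the mRNAs of other Argonautes and of the TNRC6 scaffold proteins, which Argonautes bind, AGO1 and the 3 TNRC6 mRNAs passed between Y529E and WT. AGO1 fell by 1.23 on the log2 scale (SE 0.21, adjusted p = 0.00109), TNRC6A by 1.31 (SE 0.25, adjusted p = 0.00200) and TNRC6C by 1.22 (SE 0.18, adjusted p = 0.000615), each lower in 3 of 3 arrays. TNRC6A had -0.78 after quantile scaling and -0.71 after loess, where these 3 still passed. TNRC6B had -0.88 (SE 0.26, adjusted p = 0.0186) and lost the call without Y529E-1 (0.0708), Y529E-3 (0.0785) or WT-1 (0.0681), after quantile scaling (-0.39, 0.0983) and after loess (-0.36, 0.170). AGO3 (6.56 ± 0.15 in Y529E, 7.0 ± 0.40 in WT) did not pass, with an adjusted p of 0.0839 (0.0376 without WT-3). AGO4 (6.76 ± 0.16 and 7.11 ± 0.26, adjusted p = 0.158) changed sign to 0.08 after quantile scaling and 0.09 after loess. AGO2 differed by 0.31 (SE 0.18, adjusted p = 0.234) as deposited and by 0.64 (adjusted p = 0.000896) when centred.

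Of the 15341 genes, limma called 37 higher and 4496 lower in Y529E than in WT, while the median gene differed by -0.25. After centring 2411 were higher and 2537 lower, and 2574 genes were called both ways. The split was 1415 to 1861 after quantile scaling and 1525 to 1302 after loess. Arrays did not overlap for 6819 genes (44.4%, where chance gives 10%). The total of 4533 calls fell to 2557 without Y529E-1, 2325 without Y529E-3, 2666 without WT-1 and 526 with a log2 difference of at least 1. When centred the total of 4948 fell to 2642 without Y529E-3 (1000 higher, 1642 lower) and 3124 without WT-1 (1136 higher, 1988 lower).

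**Figure D2:**
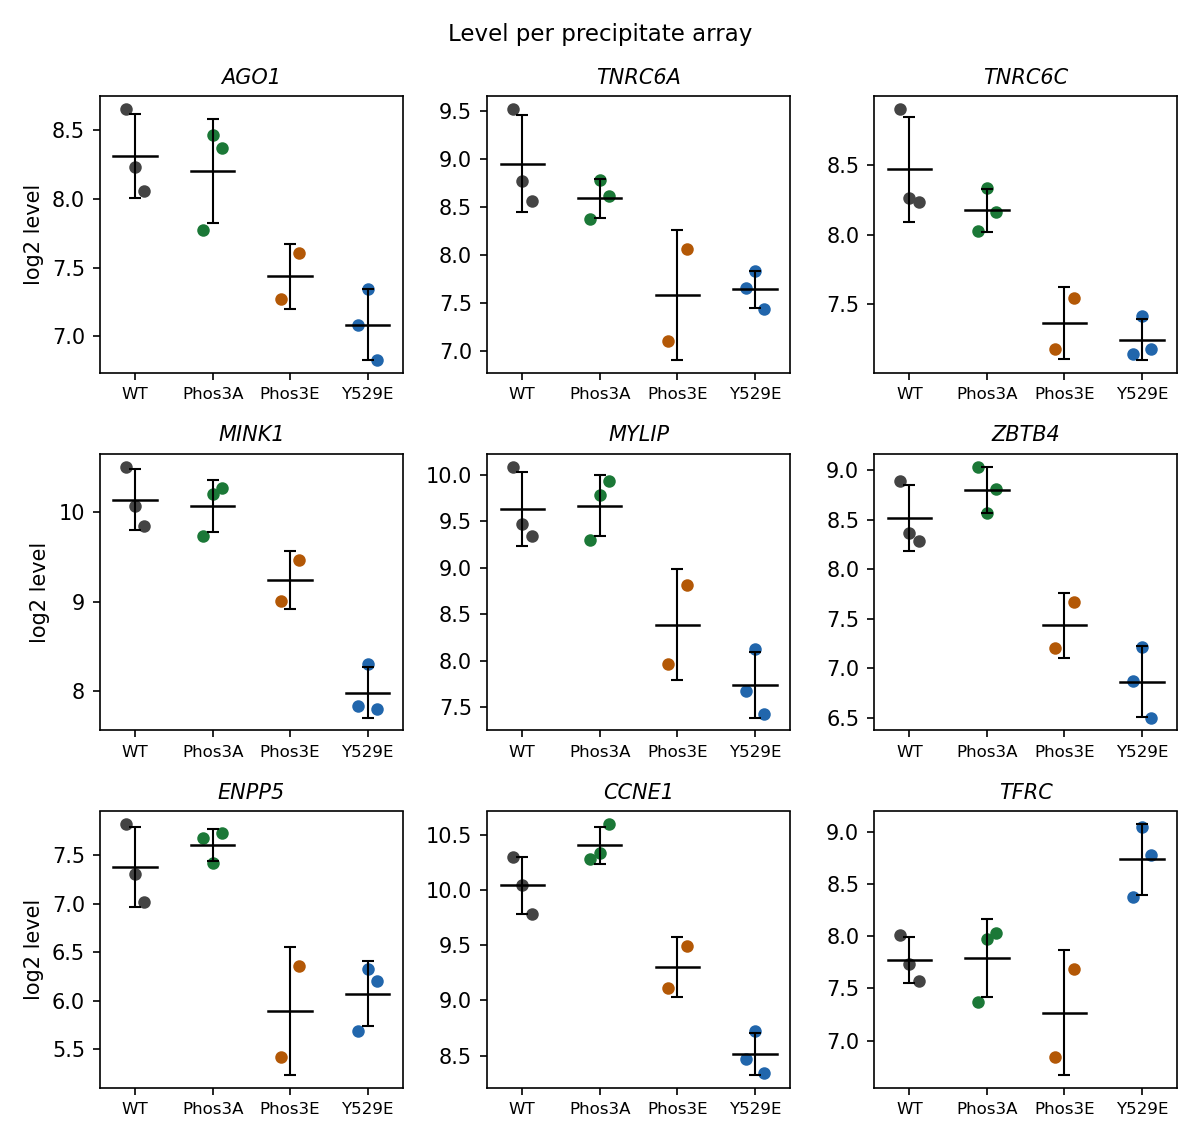
Log2 level of 9 genes on each of the 11 precipitate arrays (dots), with group means (lines) and 1 SD (error bars). In MINK1, MYLIP and ZBTB4 each of the 3 Y529E arrays lies below each of the 3 WT arrays, and TFRC lies the other way.

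Lists of microRNA targets, written in advance, were lower in Y529E than in WT relative to the median gene. Among 41 targets of the miR-17 family 30 fell (32 adjusted over the list alone), with a median of -0.45 relative to all genes (camera adjusted p = 9.93e-08, adjusted p = 0.774 with an estimated correlation). The median shrank to -0.25 after quantile scaling and -0.24 after loess. When centred 23 of them were lower and 1 higher, and ZBTB4 and ZNFX1 (-1.51) fell most. Of 37 targets of the miR-15, miR-19, miR-25 and miR-30 families (the miR-15 group) 18 fell (23 over the list alone, 12 when centred), led by MYLIP and CCNE1 (-1.53), which encodes cyclin E1. Their median was -0.27 (adjusted p = 0.000888, 0.774 with an estimated correlation), -0.10 after quantile scaling and -0.09 after loess. Of 35 let-7 targets 18 fell (20 over the list alone), against 13 lower and 4 higher when centred, led by NR6A1 and TRIM71 (-1.29), a ubiquitin ligase of stem cells. Their median was -0.37 (adjusted p = 0.00832, 0.777 with an estimated correlation). The list did not pass after quantile scaling (-0.16, 0.0871), loess (-0.14, 0.0862) or the stricter filter (-0.21, 0.0783).

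Other lists lay below the median gene too. Of 37 pathway components 20 fell (27 over the list alone, 11 lower and 1 higher when centred), with a median of -0.30 relative to all genes (adjusted p = 0.00101, 0.774 with an estimated correlation). The list did not pass after quantile scaling (-0.04, 0.148), loess (-0.02, 0.267) or the stricter filter (-0.12, 0.0807), and its median was at percentile 18.5 of 10000 random lists matched on mean level. Of 12 genes of the Argonaute phosphorylation cycle 7 fell (8 over the list alone, 5 when centred), led by ANKRD52 (-1.23) and PPP6R2 (-1.07), regulatory subunits of protein phosphatase 6. Their median was -0.32 (adjusted p = 0.0134, 0.774 with an estimated correlation), at percentile 16 of matched random lists, and the list did not pass after quantile scaling (-0.15, 0.0656), loess (-0.15, 0.0805) or the stricter filter (-0.19, 0.0774). Mitotic genes had the lowest median, -0.57 (adjusted p = 9.44e-08, 0.774 with an estimated correlation, percentile 0.02), which shrank to -0.32 after quantile scaling and -0.23 after loess. Of 31 mitotic genes 20 fell (26 over the list alone, 17 when centred), led by KIF20A (-1.40), a kinesin of cytokinesis. Of 54 nuclear genes of oxidative phosphorylation (OXPHOS) 28 fell (35 over the list alone, 16 when centred), led by the complex I genes NDUFS4 (-0.93) and NDUFS1 (-0.89), the latter not passing after quantile scaling (0.0870) or loess (0.169). Their median was -0.22 (adjusted p = 0.000236, 0.774 with an estimated correlation), at percentile 28.3 of matched random lists, and the list did not pass after quantile scaling (-0.06, 0.207), loess (-0.03, 0.490) or the stricter filter (-0.05, 0.0807).

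Some lists lay above the median gene in Y529E. The 8 mitochondrially encoded RNAs had a median 0.53 above all genes (adjusted p = 1.68e-06, 0.774 with an estimated correlation). As deposited 0 of the 8 passed (0 over the list alone), and when centred all 8 were higher. The median was 0.29 after quantile scaling and 0.93 after loess. Of 132 snoRNAs and scaRNAs 6 rose and 3 fell (0 over the list alone), against 63 higher and 1 lower when centred (median 0.30, adjusted p = 4.51e-18, 0.774 with an estimated correlation). SNORD17 fell by 0.78, and did not pass after quantile scaling (0.0770) or loess (0.0948). The call of SNORD41 (0.80) was lost without Y529E-1 (0.0612) or Y529E-3 (0.0726), that of SNORD15B (0.66) without Y529E-3 (0.107) or WT-3 (0.0523), and that of SCARNA7 (0.65) without Y529E-3 (0.0903). Of 40 spliceosomal, 7SL, Y, vault and 7SK RNAs 1 rose and 4 fell (0 and 4 over the list alone), against 14 higher and 0 lower when centred, with RNU11 (-0.69) and VTRNA1-3 (-0.65) among the lower, which did not pass when centred (0.0895 and 0.0563), after quantile scaling (0.688 and 0.0610) or loess (0.884 and 0.131). Their median was 0.29 above all genes (adjusted p = 1.67e-05, 0.774 with an estimated correlation), 0.03 as deposited, with a deposited mean of -0.04. It shrank to 0.14 after quantile scaling and 0.12 after loess. Random lists matched on mean level had 0.15 (percentile 100), and 7 markers of other cell types 0.22 (adjusted p = 0.115). The 1 RNA that rose, RNY3P2 (0.43), lost its call in each of the 6 leave-outs (0.0553 to 0.148).

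Of 300 microRNA precursors 1 rose and 10 fell (0 and 2 over the list alone), against 90 higher and 1 lower when centred (83 and 1 over the list alone), with MIR4737 (-0.94, not passing after loess, 0.0832) and MIR891A (-0.76, not passing when centred, 0.0548) lowest. The 1 that rose, MIR4748 (0.48), picked out after its value was seen, lost the call without Y529E-2 (0.201), Y529E-3 (0.0806), WT-1 (0.0632) or WT-2 (0.176). Their median lay 0.23 above all genes (adjusted p = 3.77e-13, 0.774 with an estimated correlation) although it was -0.02 as deposited. Matched random lists had 0.18 (percentile 100), and the 7 markers of other cell types 0.22, where their matched lists had 0.21. The precursor median shrank to 0.07 after quantile scaling and 0.07 after loess, where the list did not pass (0.0613). Of 23 heat shock and unfolded protein response genes 0 rose and 3 fell as deposited (2 over the list alone), among them HSPB1 (-0.63, lost under each other scaling, highest 0.919), against 10 higher and 0 lower when centred. Their median was 0.17 above all genes (adjusted p = 0.0117, 0.774 with an estimated correlation) and -0.08 as deposited. It was larger after quantile scaling (0.47, adjusted p = 9.55e-09) and loess (0.54, 8.97e-10), and the list did not pass without Y529E-2 (0.10, 0.0743) or with no filter (0.01, 0.214). Another 8 lists did not pass (adjusted p from 0.112 to 0.952). Among 22 replication-dependent histones 1 was higher and 4 lower (3 lower over the list alone), and camera pointed up although the median was -0.06 relative to all genes, as it did for p53 targets (-0.09). Lower were 6 of 47 cytosolic ribosomal proteins (3), 77 of 399 zinc finger (ZNF) genes (56), 2 of 12 nuclear-retained long noncoding RNAs (1), 9 of 29 immediate early and AU-rich mRNAs (9), 2 of 10 interferon response genes (2), 3 of 18 p53 targets (3) and 0 of 7 markers of other cell types (0), with the number adjusted over the list alone in parentheses. When centred, higher and lower were 2 and 2 histones, 1 and 2 ribosomal proteins, 36 and 35 ZNF genes, 1 and 1 long noncoding RNAs, 10 and 3 immediate early mRNAs, 2 and 0 interferon response genes, 2 and 1 p53 targets and 2 and 0 markers of other cell types.

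**Figure D3:**
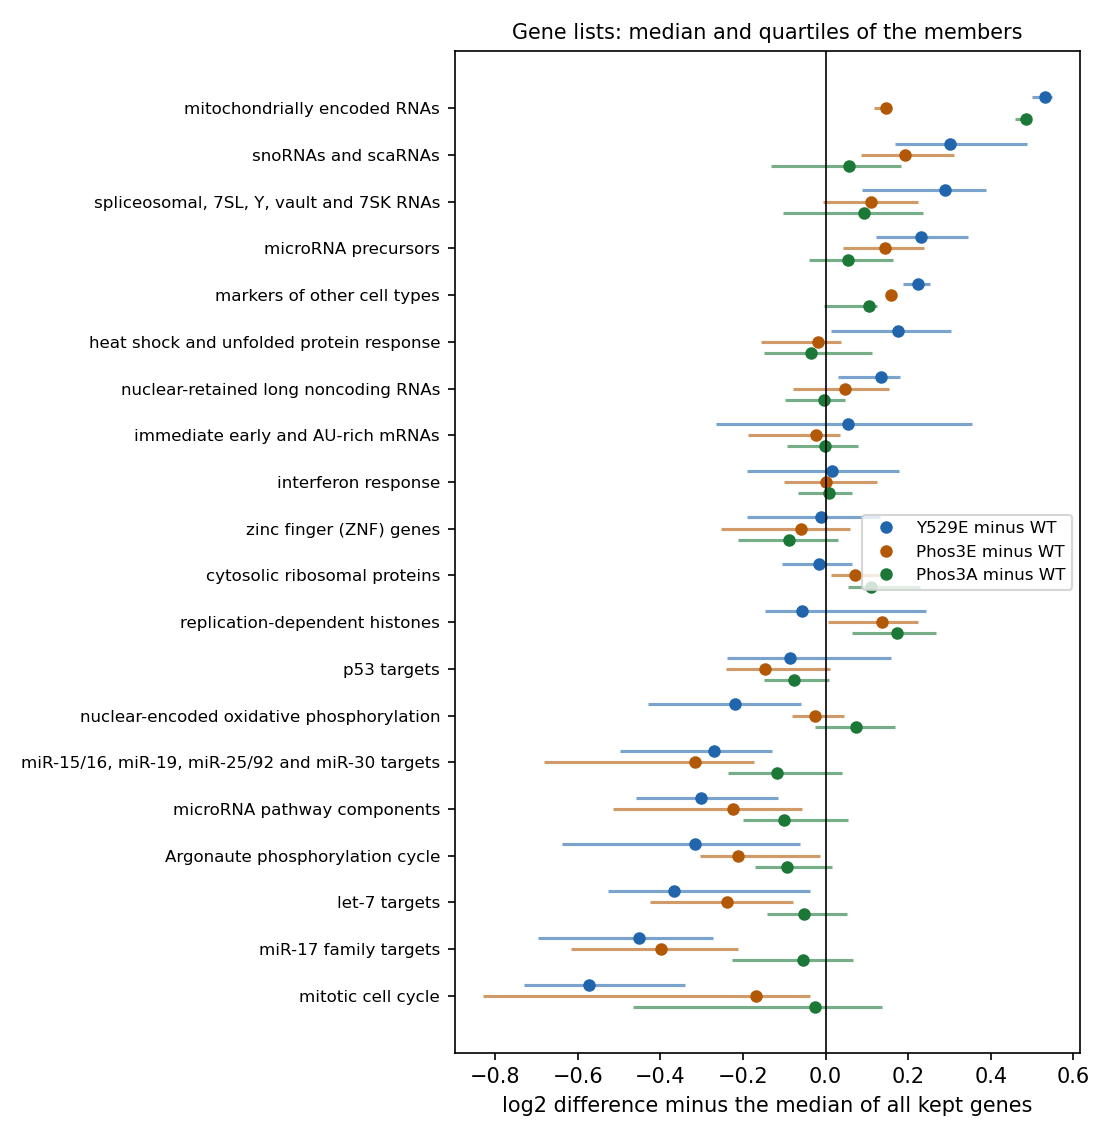
Log2 difference of the members of 20 gene lists in Y529E, Phos3E and Phos3A minus WT precipitates, after subtracting the median difference of all genes, where dots are list medians and lines run from the lower to the upper quartile. In Y529E the medians run from -0.57 for mitotic genes to 0.53 for mitochondrially encoded RNAs.

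Between Phos3A and WT precipitates no gene passed as deposited. The largest values included SRGAP2B (9.69 ± 0.68 in Phos3A, 7.79 ± 0.35 in WT, adjusted p = 0.0596) and the microRNA gene MIR3143 (9.94 ± 0.58 and 8.34 ± 0.18, adjusted p = 0.0667), n = 3 each. These were the 2 genes called when centred (adjusted p = 0.0162 and 0.0247), and SRGAP2B was picked out after its values were seen. The centred count became 422 without Phos3A-2 (326 higher, 96 lower), 1 without Phos3A-1 or WT-1, and 0 without Phos3A-3 or WT-2. MIR3143 also passed without Phos3A-2 (0.0102) or WT-1 (0.0280). Values were 8.20 ± 0.38 in Phos3A and 8.31 ± 0.31 in WT for AGO1, 7.01 ± 0.14 and 7.0 ± 0.40 for AGO3, and 7.31 ± 0.24 and 7.11 ± 0.26 for AGO4. They were 8.60 ± 0.20 and 8.96 ± 0.50 for TNRC6A, 7.83 ± 0.18 and 7.98 ± 0.67 for TNRC6B, and 8.18 ± 0.15 and 8.47 ± 0.38 for TNRC6C. limma called 0 genes, with 1997 at an unadjusted p under 0.05 (1937 higher, 60 lower) and the median gene at 0.16. When centred that unadjusted split was 1348 to 925. Arrays did not overlap for 2151 genes (14.02%). The count of 0 became 6 without Phos3A-2 and 2 without WT-1. It was 3 with the stricter filter, a trend with robust estimation or the input subtracted, 2 with only the 2 groups fitted and 1 with array weights.

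Lists of the translation and energy machinery were higher in Phos3A than in WT relative to the median gene, with 0 members past the threshold over all genes as deposited. The 8 mitochondrially encoded RNAs had a median of 0.49 (7 of 8 over the list alone, adjusted p = 3.90e-05, 0.895 with an estimated correlation), with ND2 at 13.47 against 12.78. The list did not pass after quantile scaling (0.09, adjusted p = 0.149) or loess (0.12, 0.0850). The 47 cytosolic ribosomal proteins had 0.11 (0 over the list alone, adjusted p = 0.000311, 0.895 with an estimated correlation), with RPS15 at 13.12 against 12.52. The 22 histones had 0.17 (0 over the list alone, adjusted p = 0.00401, 0.895 with an estimated correlation), and did not pass after quantile scaling (0.0906), loess (0.0700) or without Phos3A-1 (0.05, 0.488). The 54 OXPHOS genes had 0.07 (0 over the list alone, adjusted p = 0.0238, 0.895 with an estimated correlation), and did not pass after loess (0.0700) or without Phos3A-3 (0.0914). The 300 microRNA precursors had 0.05 (1 over the list alone, 1 over all genes when centred, adjusted p = 0.00584, 0.895 with an estimated correlation). They did not pass after quantile scaling (0.140), loess (0.103), with no filter (-0.00, 0.424) or without WT-1 (0.02, 0.724), and turned to -0.04 without Phos3A-1 (0.371).

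The microRNA target lists lay slightly below the median gene in Phos3A, with 0 members past the threshold over all genes or over the list alone as deposited. Medians were -0.12 for targets of the miR-15 group (adjusted p = 0.0137), -0.10 for pathway components (0.0326), -0.06 for miR-17 family targets (0.0325) and -0.09 for 399 ZNF genes (0.000311), each at adjusted p = 0.895 with an estimated correlation. As deposited these medians were above 0 (0.04, 0.06, 0.11 and 0.07). The miR-17 median was at percentile 21 of matched random lists. The first 3 lists did not pass when centred (0.0595, 0.118 and 0.120), after quantile scaling (0.207, 0.109 and 0.481), loess (0.164, 0.101 and 0.314) or the stricter filter (0.0637, 0.130 and 0.130). Nor did they pass without Phos3A-1 (0.222, 0.371 and 0.605) or WT-1 (0.726, 0.772 and 0.772), where the miR-17 median was 0.00 and 0.03. The number of lists past the threshold, 9, fell to 4 and 5 in these leave-outs. The other 11 lists did not pass (adjusted p from 0.0858 to 0.897): let-7 targets, the Argonaute phosphorylation cycle, snoRNAs and scaRNAs (1 over the list alone), spliceosomal RNAs, long noncoding RNAs, immediate early mRNAs, heat shock genes, interferon response, p53 targets, mitotic genes and markers of other cell types.

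Phos3E precipitates (n = 2) held values of several microRNA-related mRNAs below those of WT precipitates (n = 3), and 0 genes passed as deposited. TNRC6A measured 7.59 ± 0.68 in Phos3E and 8.96 ± 0.50 in WT (adjusted p = 0.0906), TNRC6C 7.36 ± 0.26 and 8.47 ± 0.38 (0.0906), and TNRC6B 6.97 ± 0.35 and 7.98 ± 0.67 (0.0948). AGO1 measured 7.44 ± 0.24 and 8.31 ± 0.31 (0.0906), AGO3 6.48 ± 0.20 and 7.0 ± 0.40 (0.144) and AGO4 6.60 ± 0.33 and 7.11 ± 0.26 (0.144). After centring 8 genes were lower and 0 higher, among them ENPP5 (5.89 in Phos3E, 7.38 in WT, centred adjusted p = 0.0441) and ZNF280B (7.92 and 9.58, 0.0401). That centred count became 474 without WT-3 (24 higher, 450 lower) and 0 without WT-1 or WT-2. limma gave 0 genes as deposited, 3718 with an unadjusted p under 0.05 (3 higher, 3715 lower), and a median gene at -0.25. The stricter filter gave 1213 and a trend with robust estimation 779, all lower. When centred the unadjusted split was 1297 to 1361. Arrays did not overlap for 7579 genes (49.4%, where chance gives 20% for 3 against 2 arrays). Without WT-3 1729 genes passed, all lower, among them TNRC6A, ENPP5 and ZNF280B (adjusted p = 0.0150 each). Fits without Phos3E-1 or Phos3E-3, here and below, leave 1 Phos3E array, with its spread taken from the other groups.

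The microRNA target lists were lower in Phos3E than in WT relative to the median gene. The miR-17 family targets had a median of -0.40 (35 of 41 over the list alone, adjusted p = 7.43e-16, 0.642 with an estimated correlation). Targets of the miR-15 group had -0.32 (27 of 37 over the list alone, adjusted p = 2.00e-09, 0.642 with an estimated correlation). The let-7 targets had -0.24 (15 of 35 over the list alone, adjusted p = 2.37e-05, 0.642 with an estimated correlation). These 3 lists passed under each scaling and with any 1 array left out, with medians of -0.26, -0.19 and -0.15 without Phos3E-1. The let-7 median was -0.13 after quantile scaling and -0.14 after loess. Members with low values included KIF5B (7.98 in Phos3E, 9.39 in WT), MYLIP (8.39 and 9.63), DICER1 (7.70 and 9.11), which processes microRNAs, and LIN28B (7.43 and 8.59), which blocks let-7 processing. In each list 0 members passed over all genes as deposited, and 1 miR-17 family target was lower when centred.

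Pathway components (median -0.22, 18 of 37 over the list alone, adjusted p = 1.91e-06) and mitotic genes (-0.17, 15 of 31, adjusted p = 1.38e-05) were lower too, both at adjusted p = 0.642 with an estimated correlation. When centred 5 pathway components and 10 ZNF genes were lower over the list alone. The mitotic median was at percentile 16.3 of matched random lists, and shrank to -0.07 after quantile scaling and -0.06 after loess. TOP2A measured 7.65 in Phos3E and 9.11 in WT. ZNF genes had -0.06 (-0.09 after quantile scaling, 33 of 399 over the list alone, 1 lower over all genes when centred, adjusted p = 0.00541, 0.835 with an estimated correlation). The Argonaute phosphorylation cycle had -0.21 (percentile 3.53, 1 of 12 over the list alone, adjusted p = 0.0481, 0.733 with an estimated correlation). It did not pass after quantile scaling (-0.14, 0.241), after loess (0.140), with the stricter filter (0.353), or without Phos3E-1 (-0.10, 0.125), Phos3E-3 (0.0542), WT-1 (0.0685) or WT-2 (0.0750).

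Small noncoding RNAs lay above the median gene in Phos3E, although their deposited medians were below WT and 0 members passed over all genes or over the list alone as deposited. The 132 snoRNAs and scaRNAs had a median of 0.19 (-0.06 as deposited, adjusted p = 1.24e-23, 0.521 with an estimated correlation). The 300 microRNA precursors had 0.14 (-0.11 as deposited, adjusted p = 4.24e-13) and 40 spliceosomal RNAs 0.11 (-0.14, 0.000107), both at adjusted p = 0.642 with an estimated correlation. Neither passed after quantile scaling (0.01 and 0.05, adjusted p = 0.329 and 0.261) or loess (0.02 and 0.06, 0.112 and 0.140), and the spliceosomal median was at percentile 80.6 of matched random lists. The histones had 0.14 (-0.12 as deposited, adjusted p = 0.00232, 0.642 with an estimated correlation) and ribosomal proteins 0.07 (-0.18, 0.00861, 0.835 with an estimated correlation). Ribosomal proteins had 0.18 after quantile scaling and 0.17 after loess, and did not pass with no filter (-0.03, 0.573). The mitochondrially encoded RNAs had 0.15 (-0.10 as deposited, adjusted p = 0.0175, 0.658 with an estimated correlation) and did not pass when centred (0.0788) or without Phos3E-3 (0.105) or WT-2 (0.10, 0.0940), or with no filter (0.05, 0.109). Markers of other cell types had 0.16 (-0.09 as deposited, adjusted p = 0.0437, 0.642 with an estimated correlation). They lay at percentile 60.3 of matched random lists, changed sign to -0.00 after quantile scaling (0.929) and did not pass when centred (0.0574), after loess (0.795) or without Phos3E-3 (0.130) or WT-1 (0.0841). The other 6 lists did not pass (adjusted p from 0.174 to 0.994): OXPHOS genes (median -0.03, camera pointing up), long noncoding RNAs, immediate early mRNAs (3 lower over the list alone), heat shock genes (4), interferon response and p53 targets.

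Phos3A and Phos3E were then compared with each other, alanine against glutamate at the same sites. ENPP5 had the largest increase in Phos3A over Phos3E (7.61 against 5.89, log2 difference 1.72, SE 0.28, adjusted p = 0.0248). It was followed by ZNF367 (1.56), the sialyltransferase ST6GALNAC6 (1.48), EEIG1 (1.38), ZBTB4 (1.37), the arrestin-domain protein ARRDC3 (1.37), PHAF1 (1.36), CNEP1R1 (1.35), SRGAP2B (1.35) and ZNF827 (1.32). Adjusted p lay between 0.0240 and 0.0259, and each of 3 Phos3A arrays lay above both Phos3E arrays. After centring 7 of these 10 passed, and ZNF367 (0.104), ARRDC3 (0.127) and SRGAP2B (0.203) did not. AGO1 (0.77), AGO2 (0.65), AGO4 (0.71), TNRC6A (1.01), TNRC6B (0.86) and TNRC6C (0.81) were higher as deposited (adjusted p from 0.0262 to 0.0408) and did not pass when centred (0.294 to 0.520). AGO2 turned to -0.07 after quantile scaling and -0.06 after loess. AGO3 measured 7.01 ± 0.14 and 6.48 ± 0.20 (adjusted p = 0.0560). MIR3143 (1.13), SNORA23 (1.06) and MIR574 (1.02) led the small RNAs as deposited and did not pass when centred (0.294 to 0.376). Without Phos3A-3 or Phos3E-1 every gene named here lost its call (0.105 or higher, and 0.345 or higher). Without Phos3A-1 so did AGO2 (0.0579), SNORA23 (0.0574) and MIR574 (0.0552), without Phos3A-2 AGO1 (0.0634) and TNRC6B (0.0771), and without Phos3E-3 MIR574 (0.0601).

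limma called 4817 genes higher and 0 lower in Phos3A than in Phos3E, with the median gene at 0.43 and 8612 genes at an unadjusted p under 0.05 (8610 higher, 2 lower). After centring 19 were higher and 2 lower, and all 19 were among the 4817. That centred count of 21 became 59 without Phos3A-1 (44 higher, 15 lower), 60 without Phos3A-2 (54 higher, 6 lower), 2 without Phos3A-3 and 0 without Phos3E-1. The 2 lower were SNORD91B (-0.79, centred adjusted p = 0.0293) and SNAR-D (-0.90, 0.0401), picked out after their values were seen. limma called 0 genes after quantile scaling (1461 unadjusted, 794 higher and 667 lower) and after loess (1504, 967 higher and 537 lower). It also called 0 with the replicate number as a block (6752 unadjusted) or without Phos3A-3 (5237). With the input subtracted 2418 passed, but that fit lacked Y529E, so the fall cannot be credited to lysate RNA. A difference of at least 1 left 154. Arrays did not overlap for 11442 genes (74.6%).

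The miR-17 family targets were higher in Phos3A than in Phos3E. As deposited 29 of 41 rose (38 over the list alone), 2 when centred, and their median was 0.31 above all genes (adjusted p = 1.24e-09, 0.975 with an estimated correlation). This list passed under each scaling and in all 5 leave-outs. Targets of the miR-15 group had 0.23 (25 of 37 higher, 29 over the list alone, adjusted p = 0.000279), among them MYLIP (1.28) and CCNE1 (1.10), and let-7 targets 0.18 (19 of 35, 28 over the list alone, 0.00648), among them NR6A1 (1.06), both at adjusted p = 0.975 with an estimated correlation. Of these members 1 and 0 were higher when centred. The 2 lists did not pass without Phos3A-2 (0.184 and 0.671) or Phos3E-1 (0.09 and 0.10, adjusted p = 0.0611 and 0.174). The let-7 list had 0.06 after quantile scaling and 0.09 after loess. Pathway components had 0.21 (23 of 37, 30 over the list alone, adjusted p = 0.00615) and mitotic genes 0.24 (16 of 31, 24 over the list alone, 0.00648), both at adjusted p = 0.975 with an estimated correlation and with 0 members past the threshold when centred. Neither passed after quantile scaling (0.08 and 0.08, adjusted p = 0.0779 and 0.286) or loess (0.08 and 0.09, 0.0815 and 0.347), without Phos3A-2 (0.285 and 0.0624) or without Phos3E-1 (0.174 and 0.183), and mitotic genes did not without Phos3A-1 (0.0728). The number of lists past the threshold, 10, fell to 3 without Phos3A-2 and 3 without Phos3E-1.

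The small nucleolar RNAs went the other way. The 132 snoRNAs and scaRNAs had a median of -0.18 relative to all genes (adjusted p = 4.31e-22, 0.597 with an estimated correlation) and 0.25 as deposited, where 12 were higher (1 over the list alone), against 0 higher and 1 lower when centred (18 lower over the list alone). This list passed under each scaling and in all 5 leave-outs. Another 4 lists passed as deposited, at adjusted p = 0.975 with an estimated correlation, and changed direction after quantile scaling, with 0 members past the threshold when centred. Among matched random lists their medians were at percentile 96.1, 10.8, 99.6 and 92.9 in the order given here. The 8 mitochondrially encoded RNAs (7 higher, 7 over the list alone) had 0.34 (adjusted p = 0.0160 and 0.975), turning to -0.02 (0.00 after loess), and did not pass without Phos3A-1 (0.618) or Phos3E-3 (0.0629). The 54 OXPHOS genes (24 higher, 41 over the list alone) had 0.05 (0.0264 and 0.975), turning to -0.01, and did not pass when centred (0.109) or without Phos3A-2 (0.0911), Phos3A-3 (0.134), Phos3E-1 (0.139) or Phos3E-3 (0.0735). The 300 microRNA precursors (49 higher, 9 over the list alone) had -0.09 (2.26e-05 and 0.975), turning to 0.04, and 40 spliceosomal RNAs (9 higher, 3 over the list alone) -0.04 (0.00914 and 0.975), turning to 0.01, where the deposited medians were 0.34 and 0.39. Neither passed without Phos3A-2 (0.256 and 0.617), Phos3A-3 (0.192 and 0.409, the spliceosomal median turning to 0.06) or Phos3E-1 (0.174 and 0.569), and spliceosomal RNAs did not when centred (0.244). After loess the precursor and spliceosomal medians were 0.02 and 0.02. The precursors and the OXPHOS genes did not pass with the stricter filter (0.01 and 0.04, 0.597 each).

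The remaining 10 lists did not pass between Phos3A and Phos3E (adjusted p from 0.409 to 0.966). Higher as deposited, with the number adjusted over the list alone in parentheses, were 5 of 12 genes of the Argonaute phosphorylation cycle (8), 9 of 22 histones (10), 19 of 47 ribosomal proteins (31), 101 of 399 ZNF genes (68) and 2 of 12 long noncoding RNAs (0). So were 15 of 29 immediate early mRNAs (17), 8 of 23 heat shock genes (12), 4 of 10 interferon response genes (5), 7 of 18 p53 targets (9, median 0.02 with camera pointing down) and 0 of 7 markers of other cell types (0). When centred 1 ZNF gene was higher and 0 members of the other 9 lists passed.

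Phos3A and Y529E precipitates differed in 7257 genes. HAND1 was higher in Phos3A by 2.17 (9.21 against 7.04, SE 0.20, adjusted p = 2.71e-05), followed by EEIG1 (2.11), MINK1 (2.09), PSME3IP1 (2.07), the Rab1 regulator TBC1D20 (2.01), NR6A1 (1.96), ZBTB4 (1.94), MYLIP (1.93), NUBP1 (1.92) and the transcription factor NFIC (1.92). All 10 passed under each scaling (1.07 to 1.51 after quantile scaling, 1.02 to 1.43 after loess) and in all 6 leave-outs, each of 3 Phos3A arrays above each of 3 Y529E arrays. Lower in Phos3A, also in every leave-out, were the xylosyltransferase GXYLT1 (-1.04), TFRC (-0.94), the cystine transporter SLC7A11 (-0.91) and STC2 (-0.87), with adjusted p from 0.00478 to 0.00857. The other 6 of the 10 largest decreases, KTN1 (-1.04), HSPA13 (-1.02), ATP2B1 (-1.02), TMTC3 (-0.91), EMC10 (-0.90) and RN5S199 (-0.84), each lost the call without Phos3A-1 or Phos3A-2 (0.0502 to 0.135). TMTC3, EMC10 and RN5S199 also lost it without Y529E-2 (highest 0.109) or Y529E-3 (0.0801), and TMTC3 without Phos3A-3 (0.0592).

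AGO1 (1.12), TNRC6A (0.95) and TNRC6C (0.93) were higher in Phos3A than in Y529E (adjusted p = 0.000620, 0.00659 and 0.000919), also when centred (0.66, 0.50 and 0.48). AGO1 had 0.51 after quantile scaling and 0.44 after loess. TNRC6A did not pass after quantile scaling (0.222) or loess (0.399), nor TNRC6C after loess (0.122). TNRC6B (0.73, adjusted p = 0.0299) and AGO4 (0.55, adjusted p = 0.0207) did not pass when centred (0.222 and 0.497), and AGO4 turned to -0.01 after quantile scaling. Both lost the call without Phos3A-3 (0.0840 and 0.104), Y529E-1 (0.0923 and 0.0589) or Y529E-3 (0.0985 and 0.0917), and TNRC6B without Phos3A-2 (0.0960). AGO3 (adjusted p = 0.0566) and AGO2 (0.766) did not pass. MIR3143 (1.40), MIR4737 (1.35) and VTRNA1-3 (1.04) led the small RNAs, and MIR3143 did not pass after quantile scaling (0.0525) or loess (0.0777). In total limma called 7225 genes higher and 32 lower, with the median gene at 0.39. When centred the split was 3098 to 2276, after quantile scaling 2438 to 2018 and after loess 2028 to 2084, and 3130 genes were called both as deposited and centred. The centred total of 5374 fell to 3543 without Y529E-3 (2329 higher, 1214 lower), and the total of 7257 to 1519 with a difference of at least 1. Arrays did not overlap for 9169 genes (59.8%).

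Of the lists, miR-17 family targets were higher in Phos3A than in Y529E (28 of 41, 32 over the list alone, median 0.49 relative to all genes, adjusted p = 0.000550, 0.801 with an estimated correlation), with ZBTB4 and ENPP5 (1.54) foremost. So were, both at adjusted p = 0.801 with an estimated correlation, mitotic genes (20 of 31, 20 over the list alone, 0.49, 0.00294), with CCNA2 (1.70), and OXPHOS genes (46 of 54, 50 over the list alone, 0.37, 1.42e-05), with COX5A (1.43), the last list not passing after loess (0.0579). These 3 medians shrank to 0.18, 0.19 and 0.13 after quantile scaling and 0.16, 0.12 and 0.12 after loess. The 47 ribosomal proteins (39 higher, 43 over the list alone, median 0.17, adjusted p = 0.00742, 0.801 with an estimated correlation) turned to -0.06 after quantile scaling (0.237) and to -0.10 after loess, where they passed the other way (0.0476), and did not pass with the stricter filter (0.01, 0.534). When centred, higher and lower were 23 and 1 miR-17 family targets, 19 and 0 mitotic genes, 23 and 0 OXPHOS genes and 8 and 1 ribosomal proteins. Mitotic genes (percentile 90.2) and ribosomal proteins (12.1) lay inside the central 95% of matched random lists.

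Below the median gene lay lists whose deposited medians were above 0, with the adjusted p followed by that with an estimated correlation (0.801 in each). The snoRNAs and scaRNAs had -0.24 (0.15 as deposited, adjusted p = 1.39e-12 and 0.801), with 18 of 132 higher as deposited (4 over the list alone) and 50 lower and 1 higher when centred. The microRNA precursors had -0.15 (0.24 as deposited, 1.42e-05 and 0.801, 58 of 300 higher, 24 over the list alone, 53 lower and 7 higher when centred), at percentile 4.71 of matched random lists, and did not pass after quantile scaling (-0.03, 0.348), loess (-0.02, 0.657) or the stricter filter (0.130). The spliceosomal RNAs had -0.21 (0.18 as deposited, 0.00294 and 0.801, 9 of 40 higher, 7 over the list alone, 8 lower and 3 higher when centred) and did not pass after quantile scaling (-0.07, 0.216), loess (-0.09, 0.277), with the stricter filter (-0.06, 0.164) or without Phos3A-2 (-0.09, 0.0623). Heat shock genes had -0.18 (0.21 as deposited, 0.00742 and 0.801, 8 of 23 higher, 8 over the list alone, 10 lower and 1 higher when centred) and -0.51 after quantile scaling and -0.59 after loess. They did not pass without Y529E-2 (0.0659) or with no filter (-0.04, 0.0637). ZNF genes had -0.07 (0.31 as deposited, 0.0412 and 0.801, 146 of 399 higher and 1 lower, 141 and 1 over the list alone, 40 higher and 74 lower when centred). They did not pass after quantile scaling (0.216), loess (-0.04, 0.350), with no filter (0.03, 0.342), or without Phos3A-1 (-0.04, 0.119) or Y529E-1 (0.102).

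The other 11 lists did not pass between Phos3A and Y529E (adjusted p from 0.0744 to 0.968). Higher as deposited, with the number adjusted over the list alone in parentheses, were 23 of 35 let-7 targets (23), 24 of 37 targets of the miR-15 group (27), 26 of 37 pathway components (31), 9 of 12 genes of the Argonaute phosphorylation cycle (9), 16 of 22 histones (16) and 0 of 8 mitochondrially encoded RNAs (0). So were 2 of 12 long noncoding RNAs (2), 13 of 29 immediate early mRNAs (14), of which 1 more was lower (1), 4 of 10 interferon response genes (4), 10 of 18 p53 targets (10) and 2 of 7 markers of other cell types (1). When centred, higher and lower were 13 and 4 let-7 targets, 9 and 1 targets of the miR-15 group, 13 and 2 pathway components, 6 and 1 genes of the phosphorylation cycle, 3 and 2 histones and 0 of the mitochondrially encoded RNAs. They were 0 and 1 for long noncoding RNAs, 3 and 7 for immediate early mRNAs, 1 and 0 for interferon response genes, 0 and 5 for p53 targets and 0 and 2 for markers of other cell types. Median and camera direction differed for immediate early mRNAs (0.04, down), interferon response genes (-0.12, up) and p53 targets (0.08, down).

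Phos3E (n = 2) and Y529E (n = 3) precipitates differed in 19 genes as deposited, depending on filter and fit. PSME3IP1 was higher in Phos3E by 1.36 (9.94 against 8.58, SE 0.20, adjusted p = 0.0318), followed by EAPP (1.29), GADD45GIP1 (1.26), the metallothionein MT1X (1.24), SARNP (1.23), the ESCRT-III subunit CHMP2A (1.14), GTF3C6 (1.14), the scavenger decapping enzyme DCPS (1.11), SPAG7 (1.10) and PDCL3P4 (1.10). TFRC (-1.47, adjusted p = 0.0477), LMTK2 (-1.08) and NEU1 (-0.95) were lower, and for these 13 genes the arrays of the groups did not overlap. All 13 passed when centred, after quantile scaling and after loess. limma called 16 genes higher and 3 lower as deposited. It called 488 with the stricter filter (262 higher, 226 lower), 225 with a trend and robust estimation (95 higher, 130 lower), 512 with only the 2 groups (311 higher, 201 lower), 2423 with array weights (1789 higher, 634 lower) and 0 with no filter (2855 at an unadjusted p under 0.05). The 19 became 0 without Phos3E-1 (1787 unadjusted), Y529E-1 (2073) or Y529E-3 (1722), 12 lower without Phos3E-3, and 23 higher without Y529E-2. All 13 genes lost the call without Phos3E-1 (0.235 to 0.254), Y529E-1 (0.111 to 0.121) or Y529E-3 (0.154 to 0.189), and all except TFRC without Phos3E-3 (0.0533 to 0.0818). Without Y529E-2 PDCL3P4 (0.0595), TFRC (0.0633), LMTK2 (0.0627) and NEU1 (0.0595) lost it. When centred the split was 1746 to 1054, after quantile scaling 1711 to 1657 and after loess 1027 to 1690. The centred total of 2800 fell to 509 without Phos3E-1 (346 higher, 163 lower), 1639 without Phos3E-3 (875 higher, 764 lower) and 1567 without Y529E-3 (973 higher, 594 lower). Arrays did not overlap for 5460 genes (35.6%). AGO2 measured 11.86 ± 0.18 and 12.44 ± 0.21 (adjusted p = 0.158).

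In this comparison no member of a list passed over all genes as deposited. Mitotic genes lay above the median gene in Phos3E (0.37, adjusted p = 0.00245, 0.956 with an estimated correlation), with 14 of 31 higher and 4 lower over the list alone, and 15 and 4 over all genes when centred. They did not pass after quantile scaling (0.24, 0.0589), loess (0.19, 0.121), with the stricter filter (0.0846) or without Phos3E-3 (0.0738). OXPHOS genes had 0.27 (0 of 54 over the list alone, 12 higher when centred, 0.000209, 0.956 with an estimated correlation). These genes had 0.16 after quantile scaling and 0.09 after loess. Ribosomal proteins had 0.10 (percentile 30.5 of matched random lists, 0 of 47 over the list alone, 3 higher when centred, 0.0406, 0.956 with an estimated correlation). They turned to -0.01 after quantile scaling and -0.03 after loess, and did not pass when centred (0.0547), with the stricter filter (0.02, 0.389) or without Phos3E-1 (0.138) or Y529E-1 (0.212).

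Below the median gene in Phos3E, with the adjusted p followed by that with an estimated correlation, were mitochondrially encoded RNAs (-0.41, 0 of 8 over the list alone, 0 when centred, adjusted p = 0.00245 and 0.956) and heat shock genes (-0.35, 2 of 23 lower over the list alone, 10 lower when centred, 0.00182 and 0.956). The first had -0.21 after quantile scaling and -0.82 after loess, and heat shock genes -0.54 after loess. Immediate early mRNAs (-0.19, 0 of 29 over the list alone, 2 higher and 4 lower when centred, 0.0220 and 0.956) did not pass with the stricter filter (0.0834) or without Phos3E-3 (0.0602) or Y529E-2 (-0.12, 0.0779). MicroRNA precursors (-0.08, 0 of 300 over the list alone, 2 higher and 4 lower when centred, 0.00289 and 0.956) did not pass after quantile scaling (-0.05, 0.238), loess (-0.03, 0.613), with the stricter filter (-0.16, 0.0904) or without Phos3E-3 (0.307). The snoRNAs and scaRNAs (-0.07, 0 of 132 over the list alone, 2 higher and 10 lower when centred, 0.0120 and 0.956) did not pass after loess (0.121) or without Phos3E-3 (0.0829) or Y529E-3 (-0.02, 0.229). ZNF genes (-0.06, 0 of 399 over the list alone, 20 higher and 33 lower when centred, 0.0406 and 0.956) did not pass after quantile scaling (0.166), loess (0.276), with no filter (-0.03, 0.163), with the stricter filter (-0.10, 0.0596), or without Phos3E-1 (0.0994) or Y529E-1 (0.129). Without Phos3E-3, 5 of the 9 lists passed. The other 11 lists did not pass (adjusted p from 0.0645 to 0.804), with medians of 0.07 for miR-17 family targets (1 higher over the list alone), 0.07 for let-7 targets (1 higher, 1 lower), -0.05 for targets of the miR-15 group (2 higher, 1 lower) and 0.07 for pathway components (0). They were 0.15 for the Argonaute phosphorylation cycle (1 higher), 0.17 for histones (1 lower), -0.13 for spliceosomal RNAs (0), -0.09 for long noncoding RNAs (0), 0.01 for interferon response genes (0), 0.03 for p53 targets (0) and -0.05 for markers of other cell types (0), and for interferon response and p53 camera pointed down. When centred, higher and lower were 11 and 3 miR-17 family targets, 8 and 3 let-7 targets, 7 and 2 targets of the miR-15 group, 1 and 2 pathway components and 3 and 0 genes of the phosphorylation cycle. They were 1 and 1 for histones, 0 and 2 for spliceosomal RNAs, 1 and 1 for long noncoding RNAs, 0 and 1 for interferon response genes, 0 and 3 for p53 targets and 0 and 0 for markers of other cell types.

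The 3 inputs had close values. Of 14105 genes bright enough in the inputs, 2 lay more than 2-fold apart between Phos3A and WT, and 0 between Phos3E and WT. The 2 were the small RNA genes RNU5B-1 (8.36 against 6.55) and SCARNA3 (7.71 against 6.51), named after their values were seen. With n = 1 each there was no test. The highest differences in Phos3A among the genes the naming rule covers were ANAPC15 (0.59), LSP1P4 (0.51) and FAM86DP (0.49), and the lowest RPS25 (-0.62), the protein kinase A subunit PRKAR1A (-0.50) and NLE1 (-0.46). In Phos3E they were LSP1P4 (0.60), RN5S134 (0.53) and HLA-DQA1 (0.39), and PRKAR1A (-0.50), RN5S395 (-0.45) and ANKRD19P (-0.40). At 5 decimals, 67.5% and 67.9% of the 14105 genes had exactly the WT value. With such ties list medians, all within 0.02 of 0, do not show unchanged lysates.

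Relative to input, the WT precipitate was richest in AGO2 (log2 ratio 3.33 after subtracting the median ratio), followed by the interleukin receptor subunit IL10RB (3.25), MINK1 (3.07), FAM222B (2.90) and MYLIP (2.89). It was poorest in the insulin receptor substrate IRS4 (-1.96), MRPL42 (-1.62), RN5S199 (-1.48) and the nuclear noncoding RNA MALAT1 (-1.41). The ratios in Phos3A and Phos3E were 3.60 and 3.49 for AGO2, 2.85 and 2.48 for MINK1, 2.78 and 1.96 for MYLIP, and -2.10 and -2.03 for IRS4. TNRC6A (2.03), TNRC6C (1.83), TNRC6B (1.12) and AGO1 (0.62) were above the median gene in WT, with 1.52, 1.38, 0.82 and 0.36 in Phos3A and 0.97, 1.03, 0.42 and 0.06 in Phos3E. AGO3 (-0.05) and AGO4 (0.10) were near it. Of 13657 genes 815 were more than 2-fold above and 58 more than 2-fold below the median ratio in WT, 910 and 137 in Phos3A, and 594 and 138 in Phos3E. The WT split was 302 and 172 after quantile scaling and 2345 and 10 with no filter. Across genes the ratio rose with the input level (Pearson r = 0.428 in WT, 0.415 in Phos3A and 0.285 in Phos3E), in inputs and precipitates that were normalized separately. There was no test, since each construct had 1 input.

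The miR-17 family targets had high ratios, with medians of 0.76 in WT, 0.68 in Phos3A and 0.31 in Phos3E (percentile 100, 100 and 97.3 among 10000 random lists matched on input level). Targets of the miR-15 group had 0.37, 0.39 and 0.24 (99.6, 99.8 and 95.6), and let-7 targets 0.39, 0.39 and 0.17 (97.6, 98.0 and 70.1). The Argonaute phosphorylation cycle had 0.58, 0.73 and 0.42 (98.1, 99.6 and 94.96) and pathway components 0.38, 0.30 and 0.37 (92.5, 74.5 and 97.6). Immediate early and AU-rich mRNAs had 0.68, 0.76 and 0.73 (100 in each) and mitotic genes 0.55, 0.55 and 0.44 (99.0, 96.1 and 97.0). Spliceosomal RNAs (-0.77, -0.70 and -0.48) and snoRNAs and scaRNAs (-0.64, -0.62 and -0.33) lay at percentile 0 in each construct. OXPHOS genes (-0.14, -0.01 and -0.14) lay at 0, 0.14 and 0.02, and ribosomal proteins (-0.07, 0.05 and 0.06) at 0.01, 0.99 and 9.10. Long noncoding RNAs had -0.39, -0.39 and -0.19 (0.26, 0.80 and 8.36), microRNA precursors -0.42, -0.35 and -0.22 (0.29, 37.8 and 24.2), and interferon response genes -0.31, -0.23 and -0.18 (4.41, 18.0 and 15.7). ZNF genes had -0.10, -0.21 and -0.14 (13.3, 0 and 0), mitochondrially encoded RNAs 0.09, 0.60 and 0.28 (16.3, 86.5 and 63.4), and p53 targets 0.15, -0.02 and 0.12 (72.1, 33.7 and 76.2). Heat shock genes had 0.21, 0.38 and 0.34 (41.3, 79.5 and 91.0), markers of other cell types -0.56, -0.46 and -0.35 (19.7, 38.0 and 16), and histones 0.07, 0.39 and 0.30 (59.9, 98.4 and 98.1).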

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

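Cyclic loess, centring combined with an estimated correlation and a wide histone pattern were chosen after the result was seen, and the other settings before. Of the settings for single genes 2856 gave the same call, 426 a weaker and 63 a stronger one, and 47 reversed the direction. For lists 633 were the same, 267 weaker and 11 reversed, and for counts and medians 180 were the same, 68 moved and 3 reversed. The counts of genes and lists rest on the scaling and on single arrays, and leave-out fits with 1 Phos3E array assume that it varies like the other groups. The cause was not tested.

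With the arrays centred, 21 genes passed for Phos3A minus Phos3E, 2 for Phos3A minus WT, 8 for Phos3E minus WT and 2800 for Phos3E minus Y529E. In Phos3E minus WT this reversed CKM (0.0862), CYTB (0.19), H2AC21 (0.00666), ND5 (0.15) and SFTPC (0.23).

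After quantile normalization limma called 0 genes for Phos3A minus Phos3E (1461 unadjusted), 4456 for Phos3A minus Y529E and 3368 for Phos3E minus Y529E. Lists past the threshold numbered 5 for Phos3A minus Phos3E, 3 for Phos3A minus WT and 5 for Phos3E minus Y529E, and 302 genes were over 2-fold above input in WT (172 below). Reversed were AGO2 in Phos3A minus Phos3E (-0.0695) and in Phos3A minus WT (-0.11), AGO4 in Phos3A minus Y529E (-0.00629) and in Y529E minus WT (0.0795), H1-4 in Phos3A minus WT (-0.0115), and CYTB (0.0393), H2BC26 (0.0505) and RNU6ATAC (0.0137) in Phos3E minus WT. So were the medians of ribosomal proteins in Phos3A minus Y529E (-0.0609), and in Phos3A minus Phos3E of microRNA precursors (0.0357), mitochondrially encoded RNAs (-0.0214), nuclear oxidative phosphorylation genes (-0.00978) and spliceosomal RNAs (0.00875). The medians of ribosomal proteins in Phos3E minus Y529E (-0.0105) and of markers of other cell types in Phos3E minus WT (-0.0012) also changed sign.

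After cyclic loess limma called 0 genes for Phos3A minus Phos3E (1504 unadjusted), 4112 for Phos3A minus Y529E, 2717 for Phos3E minus Y529E and 2827 for Y529E minus WT. Lists numbered 6 for Phos3A minus Phos3E, 2 for Phos3A minus WT and 4 for Phos3E minus Y529E. Reversed were AGO2 in Phos3A minus Phos3E (-0.0626) and Phos3A minus WT (-0.0669), AGO4 in Phos3A minus Y529E (-0.0047) and Y529E minus WT (0.0915), ASNS in Phos3A minus Y529E (-0.0311), DNAJA1 in Y529E minus WT (0.0587), and CYTB (0.0694), H2BC26 (0.0235), ND5 (0.0256) and RNU6ATAC (0.00572) in Phos3E minus WT. So were ribosomal proteins in Phos3A minus Y529E (-0.0969) and Phos3E minus Y529E (-0.0318), and in Phos3A minus Phos3E microRNA precursors (0.0221) and nuclear oxidative phosphorylation genes (-0.00197), while spliceosomal RNAs changed sign (0.0182) and mitochondrially encoded RNAs came to 0.00373.

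With a correlation estimated per list 0 lists passed in each of the 6 comparisons, also when centred. With array weights, whose fit did not reach its convergence tolerance, 1 gene passed for Phos3A minus WT and 2423 for Phos3E minus Y529E. Array weights reversed H2BC3 in Phos3E minus WT (-0.0365), and NDUFS1 (0.14), RPL37 (0.0753), SDHD (0.0298) and TNKS2 (0.12) in Phos3A minus WT. With the input subtracted, without Y529E, 2418 genes passed for Phos3A minus Phos3E and 3 for Phos3A minus WT, where RPL39 reversed (0.0215). With a minimum absolute log2 difference of 1, 154 genes passed for Phos3A minus Phos3E, 1519 for Phos3A minus Y529E and 526 for Y529E minus WT. Without a filter limma called 0 genes for Phos3E minus Y529E (2855 unadjusted) and 2345 were over 2-fold above input in WT (10 below).

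The stricter filter gave 3 genes for Phos3A minus WT, 1213 for Phos3E minus WT and 488 for Phos3E minus Y529E, 4 lists for Phos3E minus Y529E and a difference of medians there of 0.0305. A trend with robust estimation gave 3 genes for Phos3A minus WT, 779 for Phos3E minus WT and 225 for Phos3E minus Y529E. Fits to only the 2 groups gave 2 for Phos3A minus WT and 512 for Phos3E minus Y529E. With the replicate number as a block limma called 0 genes for Phos3A minus Phos3E (6752 unadjusted) and 0 for Phos3E minus Y529E (1829), and H2BC3 in Phos3E minus WT reversed (-0.00783).

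With 1 array left out, the counts of genes ran from 2325 to 5180 for Y529E minus WT, 0 to 6 for Phos3A minus WT, 0 to 1729 for Phos3E minus WT, 0 to 5634 for Phos3A minus Phos3E and 0 to 23 for Phos3E minus Y529E. Counts of lists ran from 4 to 12 for Phos3A minus WT, 3 to 8 for Phos3A minus Phos3E and 5 to 9 for Phos3E minus Y529E. The difference of medians for Phos3E minus Y529E ran from -0.13 to 0.13 and reversed without Phos3E replicate 1 (0.13) or Y529E replicate 2 (0.0669). In Phos3A minus WT the ranges were -0.11 to 0.0022 for H1-3, -0.27 to 0.16 for NDUFS1, -0.27 to 0.20 for RPL37, -0.16 to 0.14 for SDHD, -0.19 to 0.0517 for RPL39, -0.61 to 0.0755 for TNKS2 and -0.0419 to 0.13 for the microRNA precursors. In Phos3E minus WT they were -0.10 to 0.17 for FAU, -0.11 to 0.25 for H2BC11 and -0.0601 to 0.063 for H2BC3. Counts for Phos3A minus Y529E (5203 to 7695 genes, 8 to 11 lists), the lists of Y529E minus WT (11 to 13) and of Phos3E minus WT (11 to 14), and the genes over 2-fold above input in WT (821 to 846) stayed within 1.5 times. The counts for the inputs were the same under each setting run.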

Other observations

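The test of centring for the difference between Phos3A and Phos3E, the gene families, the SLC and TMEM genes and the comparison after cyclic loess were chosen after the result was seen. Families of genes that share a symbol stem, 162 with at least 10 tested genes, were compared between Y529E and WT precipitates with camera, relative to the median gene. The 75 mitochondrial ribosomal protein genes were lower (median -0.42, 59 of 75 lower as deposited, adjusted p = 2.26e-10, but adjusted p = 0.899 with an estimated correlation), also after cyclic loess (-0.19, adjusted p = 0.000109, 0.336 with an estimated correlation). The serine/threonine kinase (STK) genes were lower too (19 genes, median -0.36, 13 lower, adjusted p = 0.00305, 0.899 with an estimated correlation), at -0.24 after cyclic loess (0.00643, 0.316 with an estimated correlation).

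Families of membrane proteins lay above the median gene in Y529E. The 284 solute carrier (SLC) genes had a median of 0.19 (adjusted p = 3.81e-06, 0.899 with an estimated correlation, 2 higher and 28 lower as deposited) and 0.17 after cyclic loess (adjusted p = 3.04e-10, 0.316 with an estimated correlation). The 205 transmembrane protein (TMEM) genes had 0.18 (2.07e-05, 0.899 with an estimated correlation, 2 higher and 18 lower as deposited) and the 18 tetraspanins (TSPAN) 0.27 (0.000974, 0.899 with an estimated correlation, 0 higher and 0 lower as deposited). Over the 456 SLC and TMEM genes that the naming rule had not named, the median was 0.196, at percentile 100 of random lists matched on mean level, whose median was -0.0346. It ran from 0.157 to 0.217 when 1 array was left out. For Phos3A minus Y529E it was -0.144 and for Phos3E minus Y529E -0.146, both at percentile 0, for Phos3A minus WT 0.00606 (89.4) and for Phos3E minus WT -0.0111 (67.3). SLC and TMEM were chosen because such genes were among the largest increases, so these values restate the pattern. Whether mRNAs bound to the endoplasmic reticulum explain it stays open, as do levels in the lysate, since no Y529E input was analysed here.

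The microRNA target lists lay below the median gene in Y529E minus WT. A trend with expression level between arrays is argued against as the whole of the difference for let-7 targets (percentile 0.68 among random lists matched on mean level, whose median was -0.19 against -0.37) and miR-17 family targets (percentile 0.02, -0.23 against -0.45). It stays open for targets of the miR-15, miR-19, miR-25 and miR-30 families (3.87). After cyclic loess the medians shrank to -0.14 for let-7 targets, which missed the threshold (adjusted p = 0.0862), -0.24 for miR-17 family targets and -0.09 for the third list, so that such a trend could account for part of each. The construct itself, and what cells without tagged AGO2 would give, were not tested and stay open.

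Most genes were higher in Phos3A than in Phos3E as deposited. With the arrays centred 0.394% of the 4817 remained, but centring removes an offset by construction, so this does not decide whether an offset shared by all genes of an array explains the calls. The order of the array offsets cannot be judged, because 10 splits of the 5 arrays are too few for a share under 0.05: 1 of 10 gave a difference of medians as large as the real 0.46, and the highest other was 0.381. Whether the difference of medians is technical or a lower yield of RNA in Phos3E precipitates stays open, since the spike-in volumes followed the amount of RNA.

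Across 15341 genes, which are not independent replicates, the differences of Phos3A minus Phos3E followed those of WT minus Y529E (Pearson r = 0.446, Spearman rho = 0.454). With 1 array left out r was at least 0.336 (highest 0.525), which argues against 1 deviating array. A trend with level stays open, with r = 0.143 after cyclic loess (0.0834 without WT replicate 1), where 35 of 100 pairs of splits of the arrays were as large. Chance order of the arrays may also account for it, as 13 of 100 pairs of splits gave an absolute r as large as deposited, some of them at least 0.594. Whether both mutants lost the same bound mRNAs was not tested and stays open, and repeat precipitates of all 4 constructs, each with its own input and beside cells without tagged AGO2, would decide it.

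For the counts of called genes, 10 splits of 6 arrays are too few for a share under 0.05. In Y529E minus WT the real split gave 4533 genes and the highest other 0 (1 of 10 splits as large). In Phos3A minus Y529E it gave 7257 and the highest other 0 (1 of 10). In Phos3A minus WT limma gave 0 genes (1997 at an unadjusted p under 0.05) and the highest other 3, and since every split gives at least 0, the 10 of 10 as large decide nothing.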
